A study of Drosophila melanogaster with 24 samples.

How the data were processed

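RNA was measured in adult brains of Canton-S flies, a common wild-type strain of Drosophila melanogaster, kept on a reference diet, a diet low in branched-chain amino acids (BCAA: leucine, isoleucine and valine) or a diet high in them. Per the labels' protocols, RNA was taken from 10 brains pooled per sample with Trizol and chloroform, and libraries were made with the NEBNext low-input kit, which amplifies cDNA from small amounts of RNA. There were 24 samples, 8 per diet. The labels give a separate number to each sample of a diet, but do not say whether the pools came from separate cultures or how the sexes were mixed. The p-values therefore measure the spread between these pools.

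The deposited files hold read counts per gene, not normalized, 1 file per sample. Per the file headers, the authors counted reads with featureCounts version 1.6.4 over exons grouped by gene, against the FlyBase annotation release 6.27, with no option for strand, read pairs, multiple mapping or overlapping genes. Reads were therefore counted without regard to strand, and reads that fell on exons of more than 1 gene or mapped to several places were left out. Genes whose exons overlap a neighbour, and genes with near-identical copies, are thus under-counted by an unknown amount. Per the submitters' processing notes, reads were aligned with STAR, whose version is not given in the sources used here. The files list 17529 genes, of which 17425 were given a symbol by their FlyBase identifier and 104 kept the identifier. Coordinates are those of the files, on the Drosophila Release 6 assembly that this annotation describes, counted from 1.

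Total counts ranged from 20597740 to 36636308 in 23 libraries and were 147017 in the library of reference diet 4, where 3 counts are worth 20.4 CPM against 0.0819 to 0.146 CPM in the others. The low-input libraries carry no molecular identifiers here, so counting intervals would cover counting error only and none are given. No pair of libraries held identical values, and the most similar pair, low BCAA diet 3 and 5, had a Pearson correlation of 0.989 across genes on the log2 CPM scale, so all 24 were kept as separate samples.

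Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr over the 3 diets, which left 10288, and libraries were scaled with TMM factors. A negative binomial model with 1 mean per diet was fitted to all 24 samples with robust dispersion and quasi-likelihood estimates, leaving 21 residual degrees of freedom before moderation. The common biological coefficient of variation was 0.316. Contrasts were tested with the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Log2 fold changes (log2FC) come from this model, and their standard errors (SE) were taken as the size of the log2FC divided by the square root of F. Levels are given as CPM with TMM scaling, as mean ± SD over the 8 samples of a diet. The comparisons were each altered diet against the reference diet, high against low BCAA, any difference among the diets, and the mean of both altered diets against the reference.

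A set of 37 gene lists, for pathways fitting the brain and the diets and for cell types a dissected brain could carry along, was written before the data were examined, as were the tests, the main design and most alternatives. Names were matched to symbols through a table of names, and 8 entries were corrected by hand before any list result was looked at. Each list was tested with camera from limma 3.58.1 on log2 CPM (prior count 2), with the correlation between its genes estimated, and adjusted over the 37 lists. A preset correlation of 0.01 and fry were alternatives. The text names 12 genes fixed beforehand in each comparison. It also names the 10 risen and 10 fallen genes with the smallest p among those with adjusted p under 0.05 and a mean of at least 2 CPM, the 5 smallest p where fewer than 5 genes passed, and up to 4 passing members of each list. All other genes were named after their values were seen. These include the list members that passed only when adjusted over the list alone, an adjustment that does not correct for the number of lists.

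Alternatives were DESeq2 size factors (DESeq2 1.42.0), no filter, the DESeq2 test, limma voom with quality weights, the number in the sample titles as a block, 1 surrogate variable (sva 3.50.0), only the 16 samples compared, only genes with a mean of at least 10 CPM for the correlation between diets, and each sample left out in turn. The DESeq2 test started from all genes of the files and not from the 10288 left by filterByExpr. Leaving out the libraries of reference diet 4 and low BCAA diet 8, alone, with 1 surrogate variable or with 4 more, was chosen after seeing the data. The test was also run on simulated data for 10288 genes with the real means, library sizes and dispersions, in which 200 genes differed between low BCAA and reference: it recovered 44% of those changed 1.5-fold and 78% of those changed 2-fold, with 8 false calls. The overlap of low and high BCAA calls was set against 100 simulated draws of unchanged libraries and 100 shuffles of the diet labels, both with a shared reference group, which was decided after the overlap was seen. A check of GC content was not made, since no genome sequence was used here.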

Results

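Gene expression was measured by RNA sequencing in pools of 10 adult brains from Canton-S flies fed a reference diet, a diet low in branched-chain amino acids (BCAA) or a diet high in them, with 8 samples per diet. The series is about hunger, histone modifications in neurons and aging, and this part of it compares brain transcripts among the 3 diets. Total counts ranged from 20597740 to 36636308 in 23 libraries. Between 12374 and 12968 genes had at least 1 count in 22 of these. The library of low BCAA diet 8 held 21658878 counts but only 10632 detected genes. The library of reference diet 4 held 147017 counts and 8749 detected genes, so that 3 counts were worth 20.4 CPM there. Yp2, which encodes a yolk protein, or the noncoding RNA lncRNA:noe had the highest count in 21 libraries. In the other libraries, reference diet 3, high BCAA diet 3 and high BCAA diet 5, the uncharacterised gene CG34220 took 6.90%, 5.66% and 3.92% of counts. The first principal component held 50% of the variance of all 24 libraries and 26.8% without reference diet 4 and low BCAA diet 8.

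**Figure D1:**
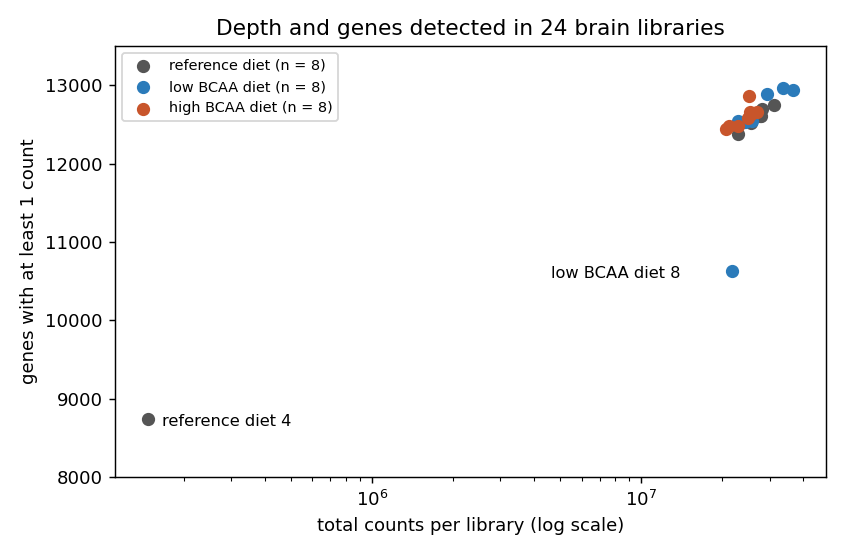
Genes with at least 1 count against total counts (log scale) for each of the 24 libraries, coloured by diet. Reference diet 4 stands apart at 147017 counts, and low BCAA diet 8 has 10632 detected genes at 21658878 counts.

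The first comparison asked which transcripts differed when BCAA were scarce. In brains from the low BCAA diet edgeR called 21 genes that fell and 0 that rose against the reference diet, of 10288 tested. Other tests also called rises (22 of 139 genes with DESeq2, which started from all genes of the files, and 310 of 861 with limma voom and quality weights). EndoA, which encodes the endophilin that acts in synaptic vesicle endocytosis, was at 91.6 ± 19.3 CPM on the reference diet and 56.2 ± 6.95 CPM on the low BCAA diet (mean ± SD, n = 8 per diet), a log2FC of -0.70 ± 0.12 (SE). Ilp5, which encodes an insulin-like peptide made by the insulin-producing cells of the brain, fell from 95.3 ± 42.2 to 49.6 ± 9.10 CPM, a log2FC of -0.82 ± 0.16. Gagr, a gene derived from the gag gene of a retrotransposon, fell from 8.91 ± 3.47 to 2.55 ± 1.11 CPM, a log2FC of -1.69 ± 0.26. Its reference mean includes 14.6 CPM in reference diet 4, where 3 counts are worth 20.4 CPM. With each library left out in turn its log2FC ran from -1.86 to -1.58 and the call held. Obp99b, of the odorant-binding protein family, fell from 1728 ± 988 to 193 ± 188 CPM, a log2FC of -3.17 ± 0.66. For each of these genes all 8 low BCAA samples lay below the reference median, and the edgeR adjusted p was 0.0084 for EndoA, 0.026 for Ilp5, 0.0039 for Gagr and 0.048 for Obp99b.

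The smallest p belonged to CG1275, which fell from 47.3 ± 9.41 to 33.3 ± 2.20 CPM (log2FC -0.56 ± 0.08, edgeR adjusted p = 0.0013). FucT6, a fucosyltransferase gene, had a log2FC of -0.35 ± 0.06 (150.3 ± 15.1 to 119 ± 8.20 CPM). HPS4, which encodes a member of a complex for lysosome-related organelles, had -0.42 ± 0.08, and Tango5 -0.35 ± 0.07. The others named by the fixed rule were pippin, a transporter of the sugar transporter family (-0.57 ± 0.09), CG9743, a predicted fatty acid desaturase (-0.47 ± 0.08), CG3168 (-0.50 ± 0.09, from 359.5 ± 30.4 to 255 ± 43.6 CPM) and CG12256 (-0.78 ± 0.15). The edgeR adjusted p of these genes ran from 0.0041 for pippin to 0.026 for Tango5. In each case all 8 low BCAA samples lay below the reference median. Exons of other genes overlap 79.2% of the exons of pippin, 85.1% of those of CG12256 and 14.9% of those of HPS4, so their values are uncertain. The remaining called genes, named after their values were seen, were CG14687, Ubqn, CG6293, MtnA, CHMP2B, mthl2, Der-1, Arfip and CG15506, with log2FC from -0.32 for Arfip to -2.18 for CG15506. On the Release 6 assembly EndoA spans 18906609 to 18910755 and Obp99b 29716254 to 29716896 of chromosome 3R. On chromosome 3L, Ilp5 spans 9823349 to 9823897, Gagr 16394586 to 16396880 and CG1275 2252744 to 2257423.

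**Figure D2:**
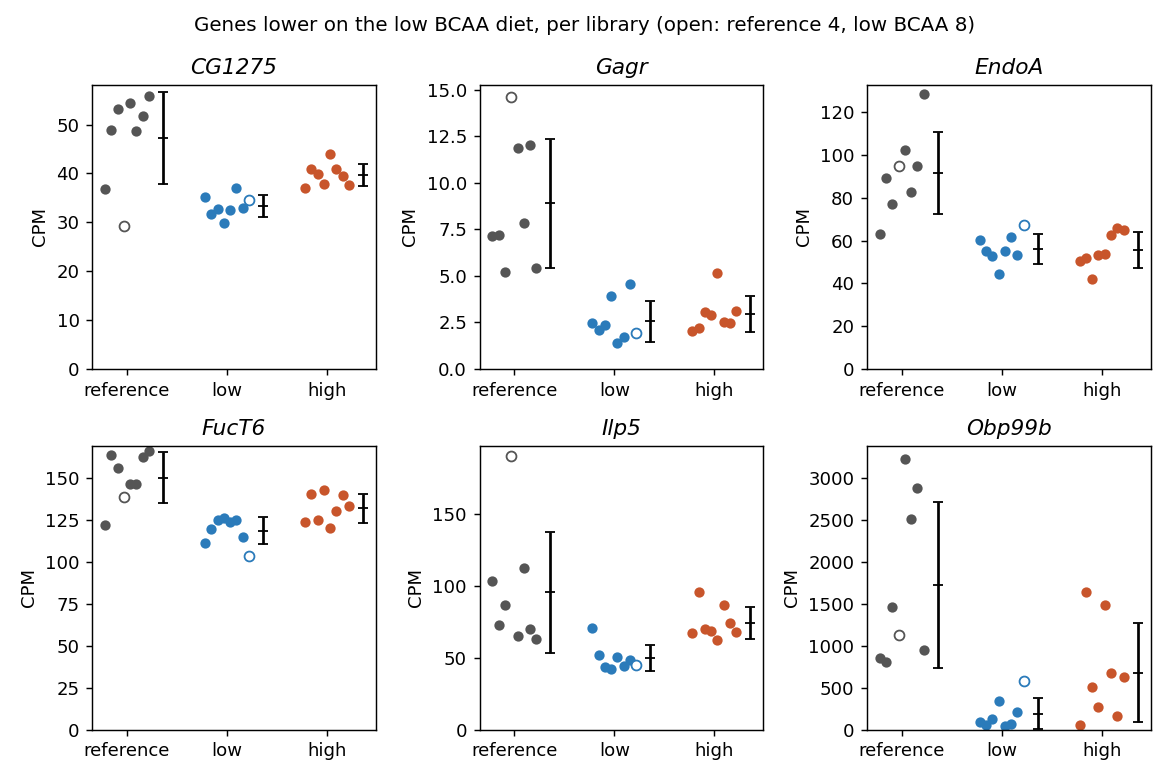
CPM of CG1275, Gagr, EndoA, FucT6, Ilp5 and Obp99b in each library by diet, with each point a library (open for reference diet 4 and low BCAA diet 8) and the black mark and bar the mean and SD of 8 libraries. EndoA and Gagr are lower on both altered diets than on the reference diet, and Ilp5 has means of 95.3, 49.6 and 74.0 CPM on the reference, low and high BCAA diets.

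Of 20 insulin signalling genes tested, Ilp5 fell and 19 did not pass, and 1 passed when adjusted over the list alone. Ilp2 had a log2FC of -0.52 ± 0.19 (edgeR adjusted p = 0.27, 8 of 8 samples lower) and Ilp3 -0.44 ± 0.16 (0.27, 7 of 8 lower). InR, the insulin receptor gene, had -0.07 ± 0.10. The reference mean of Ilp5 includes 190 CPM in reference diet 4, the library of few counts, against a next highest of 112 CPM. Without that library and low BCAA diet 8 its log2FC was -0.72 (edgeR adjusted p = 0.013). Of the genes of BCAA breakdown 13 of 15 had a log2FC below 0, with a median of -0.17, and none passed by either adjustment. Bcat, the aminotransferase that starts this pathway, had a log2FC of -1.19 ± 0.47 (edgeR adjusted p = 0.30, 7 of 8 lower). Its reference mean of 5.40 ± 9.68 CPM includes 29.2 CPM in reference diet 4. The amino acid stress genes under the transcription factor ATF4 had 14 of 21 members below 0 and 0 passing by either adjustment. Gcn2, a sensor kinase for uncharged tRNA, was at 0.03 ± 0.10. Thor, the 4E-BP homolog, had a log2FC of 0.08 ± 0.59, the amino acid transporter slif -0.35 ± 0.31, NPF 0.01 ± 0.16 and sNPF -0.07 ± 0.10. The histone H3.3 genes His3.3A and His3.3B had log2FC of 0.09 ± 0.10 and 0.02 ± 0.05. None of 19 histone variant genes, 19 acetyltransferase genes or 23 methylation genes passed by either adjustment. Among 15 deacetylase and corepressor genes none passed over all genes and 1, MTA1-like at -0.26 ± 0.07, passed when adjusted over the list alone.

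Of 32 synaptic transmission genes EndoA alone fell, while 27 had a log2FC above 0 with a list median of 0.13. Adjusted over the list alone 2 passed, EndoA and cpx (complexin, 0.24 ± 0.06, edgeR adjusted p over all genes = 0.060). Marker genes of neurons lay above 0 in 11 of 16 cases, with futsch at 0.39 ± 0.11 the 1 that passed when adjusted over the list alone. Genes of serotonin, dopamine and octopamine lay above 0 in 23 of 25 cases with a median of 0.13, and 0 passed by either adjustment. Photoreceptor markers, which a brain dissected with retina would carry, lay above 0 in 20 of 21 cases with a median of 1.02, and 0 passed by either adjustment. Fat body markers lay below 0 in 11 of 16 cases with a median of -0.46. Obp99b fell, and adjusted over the list alone 2 passed, Obp99b and regucalcin (-0.58 ± 0.19). Hemocyte markers lay below 0 in 14 of 15 cases with a median of -0.41. None passed over all genes and 2 when adjusted over the list alone, crq (-0.56 ± 0.13) and NimC1 (-0.81 ± 0.24). Cytosolic ribosomal protein genes lay below 0 in 79 of 85 cases with a median of -0.11, where RpL29 (-0.51 ± 0.12) was the 1 that passed when adjusted over the list alone. In the fasting and sugar response list of 20 genes, median -0.29, Obp99b was the only fall, and the only one when adjusted over the list alone.

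In the other lists 0 genes passed over all genes tested. Adjusted over the list alone 1 passed in each of 4 lists: Hug, a neuropeptide gene (0.49 ± 0.12), dco of the circadian clock (-0.39 ± 0.09), Hsc70-3, the chaperone BiP of the endoplasmic reticulum (-0.43 ± 0.13), and GstD2 (-1.70 ± 0.45). Oxidative stress and detoxification genes, which include GstD2, lay below 0 in 31 of 36 cases with a median of -0.22. Heat shock and chaperone genes had a median of 0.01, although the list test pointed down. The median log2FC was -0.01 for TOR and GATOR signalling, -0.03 for amino acid transporters, 0.01 for neuropeptides, 0.08 for their receptors and -0.05 for the circadian clock. It was -0.25 for antimicrobial genes, 0.14 for glycolysis and trehalose metabolism and 0.04 for oxidative phosphorylation. For mitochondrial ribosomal proteins it was -0.04, for the proteasome -0.07, for aminoacyl-tRNA synthetases -0.03 and for autophagy and lysosome -0.09. For acetyl-CoA and lipid synthesis it was -0.13, for one-carbon metabolism -0.11 and for neuronal activity-regulated genes -0.01. Markers of glia had a median of 0.07, muscle 0.19, antenna and proboscis 0.48 and corpora cardiaca and allata -0.10, and sex-biased transcripts -0.02.

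As groups, 0 of 37 lists passed with camera and an estimated correlation, and fry also called 0. Insulin signalling had the smallest camera p (0.037, adjusted p = 0.738) and was the 1 list under 0.05 before adjustment. Of its genes 10 lay below 0 and 10 above, with a median log2FC of -0.01. With a preset correlation camera called 14 lists, led by cytosolic ribosomal proteins (adjusted p = 2.18e-06), hemocytes (0.000655), synaptic transmission (0.00118) and photoreceptors (0.00296). The same 4 lists had an adjusted p = 0.738 with an estimated correlation, and none of the preset calls of this or the later comparisons held. For genes the edgeR count of 21 stood beside 1307 at an unadjusted p under 0.05, where chance gives 514. It was 11 with only the 16 samples compared, 13 without a filter on low counts and 46 with the sample number as a block (18 of the 21 kept). It was 92 with 1 surrogate variable (18 risen), 139 with DESeq2 and 861 with limma voom. The count was 116 without reference diet 4 and low BCAA diet 8 (9 risen), 80 without reference diet 4, 69 without reference diet 1 or low BCAA diet 8, 43 without low BCAA diet 4 and 6 without low BCAA diet 2. With 1 library left out, the adjusted p of Ilp5 reached 0.0657 (without low BCAA diet 2, 3, 5 or 6 or reference diet 6 it no longer passed) and that of Obp99b 0.123, and with only the 16 samples compared that of Ilp5 was 0.107.

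**Figure D3:**
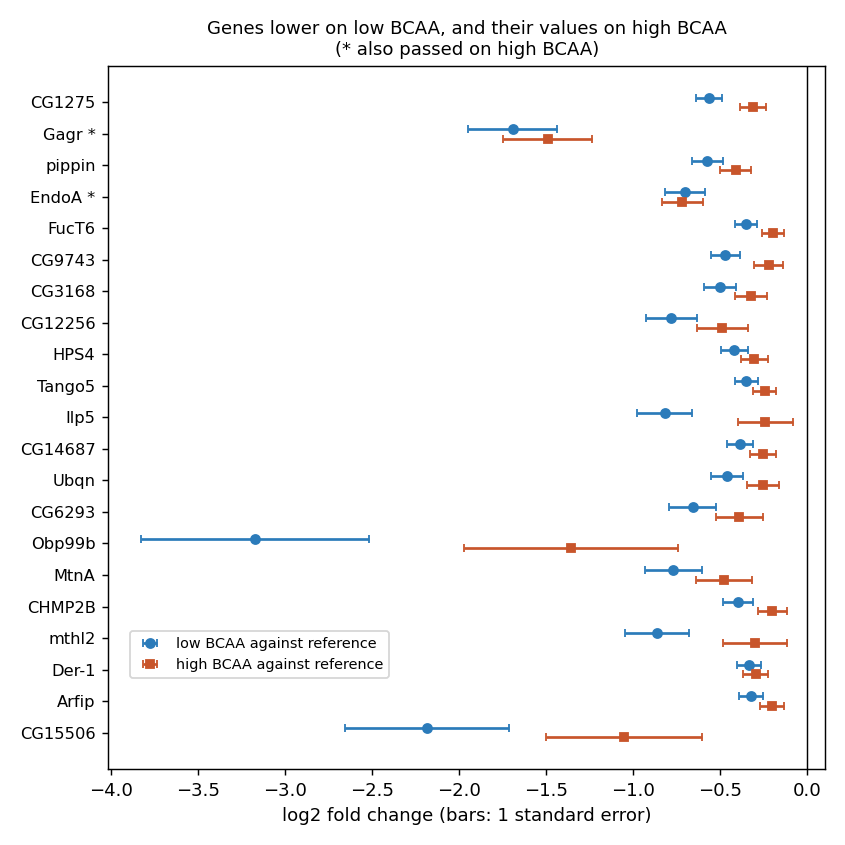
Log2 fold changes with SE of the genes called in low BCAA against reference, shown for the low BCAA diet and the high BCAA diet. All 21 lie below 0 on both diets, which were set against the same 8 reference libraries.

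The next comparison asked what an excess of BCAA altered. On the high BCAA diet 2 genes fell and 0 rose against the reference diet, and both were also among the falls on the low BCAA diet. EndoA fell to 55.7 ± 8.25 CPM (log2FC -0.71 ± 0.12, edgeR adjusted p = 0.025) and Gagr to 2.94 ± 0.97 CPM (-1.49 ± 0.26, adjusted p = 0.025), each lower than the reference median in 8 of 8 samples. The next smallest p-values did not pass. They were those of meigo, a gene of the endoplasmic reticulum (-0.56 ± 0.12, 90.5 ± 18.8 to 61.2 ± 8.94 CPM), pippin (-0.41 ± 0.09) and Grp170, a chaperone gene of the same organelle (-0.39 ± 0.09, 281 ± 55.4 to 216 ± 17.6 CPM). Their edgeR adjusted p was 0.30, 0.30 and 0.37, with 8 of 8 samples lower for each. Ilp5 stood at 74.0 ± 11.4 CPM with a log2FC of -0.24 ± 0.16 (6 of 8 lower), Ilp2 at -0.12 ± 0.19 and Ilp3 at -0.10 ± 0.16. Bcat had a log2FC of 0.17 ± 0.46 although its mean was lower than on the reference diet (2.56 ± 0.97 against 5.40 ± 9.68 CPM). That reference mean rests on 29.2 CPM in reference diet 4, and the log2FC was 0.36 ± 0.38 without this library and -0.02 without reference diet 8, so its direction was not settled. For slif the log2FC was -0.28 ± 0.31, for InR 0.12 ± 0.10 and for Thor 0.14 ± 0.59. His3.3A had 0.10 ± 0.10, His3.3B -0.02 ± 0.05, NPF -0.02 ± 0.16 and sNPF 0.06 ± 0.10, and the edgeR adjusted p of each of these genes was 1.00. Gcn2 lay at its reference level within an SE of 0.10.

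Of the lists, synaptic transmission held the single fall of EndoA, also the 1 that passed when adjusted over the list alone, with 26 of 32 members above 0. The 36 other lists held 0 genes that passed over all genes. Adjusted over the list alone, 1 gene each passed among neuropeptides (Hug, 0.44 ± 0.12), chaperones (Hsc70-3, -0.44 ± 0.13), fasting and sugar response and fat body (tobi, a glucosidase, 2.49 ± 0.64 in both) and antenna and proboscis (Orco, the odorant co-receptor, 1.22 ± 0.37). Antennal markers lay above 0 in 13 of 13 cases with a median of 0.89, muscle markers in 18 of 22 with a median of 0.53, and photoreceptor markers in 19 of 21 with a median of 0.42. Fat body markers lay below 0 in 11 of 16 cases with a median of -0.33, and hemocyte markers in 13 of 15 with a median of -0.20. BCAA breakdown genes lay above 0 in 11 of 15 cases with a median of 0.07. Insulin signalling genes lay below 0 in 14 of 20 cases with a median of -0.04, and cytosolic ribosomal protein genes below 0 in 62 of 85 with a median of -0.04. The medians of the deacetylase (0.03), circadian (0.002) and corpora cardiaca (0.02) lists were above 0 where the list test pointed down. Those of the one-carbon (-0.006), ATF4 (-0.004) and aminoacyl-tRNA synthetase (-0.0025) lists were below 0 where it pointed up.

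As groups, 0 of 37 lists passed with camera or with fry. The 11 sex-biased transcripts had the 1 unadjusted p under 0.05 (0.032, adjusted p = 0.958), and fat body markers were the only list called with the preset correlation (adjusted p = 0.013, against 0.958 with an estimated correlation). The edgeR count of 2 stood beside 437 genes at an unadjusted p under 0.05, fewer than the 514 that chance gives. It was 1 with only the 16 samples compared, 4 with 1 surrogate variable, 21 with DESeq2 (4 risen) and 30 with limma voom and quality weights (0 risen). The call of EndoA ended without any 1 of 6 libraries (reference diet 5 or 7, high BCAA diet 1, 2, 3 or 4; highest adjusted p 0.0969) and that of Gagr without any 1 of 10 (reference diet 5, 6 or 7, all high BCAA libraries but 5; highest adjusted p 0.117).

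The 2 altered diets were then set against each other, a comparison that does not use the reference mean. No gene passed. The smallest p belonged to CG4269, at 0.329 ± 0.364 CPM on the low and 3.06 ± 2.76 CPM on the high BCAA diet (log2FC 3.15 ± 0.63, 7 of 8 samples higher, edgeR adjusted p = 0.31). The methuselah-like receptor gene mthl10 was at 9.94 ± 1.26 and 16.2 ± 4.70 CPM (0.70 ± 0.15, 8 of 8 higher, adjusted p = 0.31). The cytochrome P450 gene Cyp4ac3 was at 11.98 ± 3.35 and 20.2 ± 6.06 CPM (0.75 ± 0.17, 8 of 8 higher, adjusted p = 0.45). Mdr49, an ABC transporter gene, had a log2FC of 0.34 ± 0.08 (adjusted p = 0.66) and Tspo 0.45 ± 0.11 (0.98), with 75% of the exons of Tspo overlapped by other genes. Ilp5 was at 49.6 ± 9.10 CPM on the low and 74.0 ± 11.4 CPM on the high BCAA diet (0.58 ± 0.15, 8 of 8 samples higher), with an edgeR adjusted p of 1.00 over all genes and 0.019 over the insulin signalling list. Bcat had a log2FC of 1.35 ± 0.45 (1.01 ± 0.62 to 2.56 ± 0.97 CPM, 7 of 8 higher, adjusted p = 1.00). Ilp2 had 0.40 ± 0.18, Ilp3 0.34 ± 0.16, InR 0.20 ± 0.10, sNPF 0.13 ± 0.10 and slif 0.08 ± 0.31. Thor had 0.06 ± 0.57, His3.3A 0.01 ± 0.10, His3.3B -0.04 ± 0.05, Gcn2 -0.03 ± 0.10 and NPF -0.03 ± 0.16.

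All 37 lists held 0 genes that passed over all genes. Adjusted over the list alone, 1 gene passed in each of 3 lists, namely Ilp5, Pdfr, the receptor of a clock neuropeptide (-0.24 ± 0.07), and Arc1, an activity-regulated gene (0.89 ± 0.24). With 37 lists each adjusted separately, chance alone can give such genes. BCAA breakdown genes lay above 0 in 14 of 15 cases with a median of 0.21. ATF4 genes lay above 0 in 19 of 21 cases with a median of 0.10, and 0 passed by either adjustment. Among them, named after their values were seen, were the serine synthesis gene aay at 0.64 ± 0.23 and the asparagine synthetase gene AsnS at 0.33 ± 0.15. Proteasome genes lay above 0 in 32 of 34 cases (median 0.08), cytosolic ribosomal protein genes in 78 of 85 (0.07), detoxification genes in 31 of 36 (0.15) and hemocyte markers in 14 of 15 (0.24). Synaptic genes lay below 0 in 29 of 32 cases (median -0.08), neuron markers in 15 of 16 (-0.04) and photoreceptor markers in 20 of 21 (-0.57). Amino acid transporters had a median of -0.04 where the list test pointed up.

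As groups, 0 of 37 lists passed with camera (ATF4 genes had the 1 unadjusted p under 0.05, at 0.046, adjusted p = 0.688) or with fry. The preset correlation called 14 lists, among them ATF4 (adjusted p = 0.000353) and BCAA breakdown (0.000233), both with an adjusted p = 0.688 with an estimated correlation. For genes the edgeR count of 0 stood beside 431 at an unadjusted p under 0.05, fewer than the 514 that chance gives. The count was 4 with DESeq2 and 2 with limma voom and quality weights. DESeq2 called CG4269 and mthl10 (adjusted p = 0.0083 and 0.047), and voom called Mdr49 (0.0091). Without high BCAA diet 4 edgeR called 1 gene, CG4269 (adjusted p = 0.041).

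With both altered diets against the reference, 21 genes fell and 0 rose, 12 of them also called on the low BCAA diet. The 9 others, named after their values were seen, included Grp170 with a log2FC of -0.38 ± 0.08, the co-chaperone gene P58IPK with -1.03 ± 0.20 and meigo with -0.56 ± 0.10, each with an edgeR adjusted p of 0.029. Der-1, which encodes a protein of the export of misfolded proteins from the endoplasmic reticulum, fell on the low BCAA diet and in this comparison (-0.31 ± 0.06, adjusted p = 0.029). NUCB1 had -0.31 ± 0.06, CG16965 -1.19 ± 0.24, CG31342 -0.44 ± 0.09, CG30384 -1.60 ± 0.33, CG13585 -0.34 ± 0.07 and CG1299 -3.83 ± 0.78. EndoA had -0.71 ± 0.10 (adjusted p = 0.0011) and Gagr -1.59 ± 0.21 (0.00084). Beside these, hemocyte markers had median log2FC of -0.41 and -0.20, and fat body markers -0.46 and -0.33, on the low and high BCAA diets. The edgeR count of 21 stood beside 958 genes at an unadjusted p under 0.05, where chance gives 514. It was 10 without a filter on low counts (9 of the 21 kept) and 40 with the sample number as a block (18 of the 21 kept). It was 61 with 1 surrogate variable (1 risen), 100 with DESeq2 (10 risen) and 298 with limma voom (36 risen). It was 89 without reference diet 4 and low BCAA diet 8, 79 without reference diet 1, 53 without reference diet 4, 45 without low BCAA diet 8, 34 without low BCAA diet 4 or high BCAA diet 5, 5 without reference diet 5 or 6 or low BCAA diet 1, 9 without reference diet 3 or low BCAA diet 6, 12 without low BCAA diet 5, and 4 without reference diet 7. A test of any difference among the 3 diets called 4 genes, CG1275, Gagr, EndoA and pippin, all 4 among the 21 called on the low BCAA diet. This count stood beside 809 at an unadjusted p under 0.05, where chance gives 514. It was 18 with the sample number as a block, 24 with 1 surrogate variable, 257 with DESeq2 and 312 with limma voom.

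Across the 10288 genes, which are not independent replicates, the log2FC of the low and high BCAA diets had a Pearson correlation of 0.564 and a covariance of 0.0780. Both used the same reference libraries. Simulated sets of 24 unchanged libraries, with a shared reference group that was simulated as well, gave a mean correlation of 0.513 (0.407 to 0.628 over 100 draws). Their mean covariance was 0.0454, which lies 0.0326 below the observed one. With the diet labels shuffled over the 24 libraries, which keeps the correlation between genes, the mean correlation was 0.497 (0.104 to 0.847 over 100 draws) and the mean covariance 0.0763 (0.0128 to 0.224), so the observed covariance was not above that value by more than its spread. When each diet was set against a separate set of 4 reference libraries, the mean correlation over 35 splits was -0.083 (from -0.177 to -0.015), and -0.101 without reference diet 4. With 1 split drawn at random each time, simulated unchanged libraries gave a mean of 0.0347 (-0.0818 to 0.134) and shuffled labels 0.0150 (-0.379 to 0.472) over 50 draws each. Without reference diet 4 these were 0.0379 (-0.0528 to 0.178) and 0.123 (-0.397 to 0.614). The observed means lay below all simulated draws, which carry no correlation between genes, and inside the range of the shuffles. A mean over 35 splits is unlike a draw of 1 split, and single observed splits reached -0.015, or -0.0213 without reference diet 4, inside the simulated ranges. The splits thus gave no sign of a shared direction and left open whether the diets differ in opposite directions. Both genes called on the high BCAA diet, EndoA and Gagr, were among the 21 called on the low BCAA diet. Independent lists would share 0.0041 genes, but these lists share their reference libraries: the 2 genes of smallest p in the high BCAA comparison were both among the 21 of smallest p in the low BCAA comparison in 11 of 100 simulated draws and 18 of 100 shuffles. All 21 had a log2FC below 0 on the high BCAA diet, where the 21 genes of smallest p all kept their direction in 40 of 100 simulated draws and 33 of 100 shuffles. An unadjusted p under 0.05 on the high BCAA diet was found for 19 of the 21, against a mean of 9.98 (4 to 15) in simulated draws and 8.84 (0 to 21) in shuffles, of which 6 of 100 reached 19.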

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

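The tests of why low BCAA diet 8 had few detected genes were chosen only after that result was seen. Among 96 groups of 8 libraries (depth, detected genes and 30 named genes, by diet), 17 held a library whose gap to its neighbour, as a share of the range of its group, was above Dixon's 95% critical value for groups of 8. Chance gives about 1 in 20 groups, or 4.8 here. Of the 17 groups, 11 were set apart by reference diet 4.

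Reference diet 4 had the lowest total (147017 counts, a gap of 0.732 of the range) and the fewest genes detected on its diet (8749, 0.907). It also had the highest CPM of Ilp2 (161, 0.814), Ilp3 (343, 0.529), Ilp5 (190, 0.614), Bcat (29.2, 0.864), InR (124, 0.729) and Gcn2 (73.0, 0.733). The same library had the lowest CPM of His3.3A (21.9, 0.756), NPF (0, 0.805) and Tspo (7.30, 0.587). With 3 counts worth 20.4 CPM there, 0 counts allow NPF up to that level in this library, so its place among the reference libraries is not measured.

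Outside that library, reference diet 7 had the highest CG3168 of its diet (429 CPM, 0.644), low BCAA diet 1 the highest Ilp5 (70.4 CPM, 0.652), low BCAA diet 4 the highest Bcat (2.35 CPM, 0.568), low BCAA diet 7 the highest Cyp4ac3 (19.4 CPM, 0.596) and high BCAA diet 5 the highest Gagr (5.13 CPM, 0.651). These values were not followed up.

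Low BCAA diet 8 had the fewest genes detected of its diet (10632, a gap of 0.815 of the range), at a total of 21658878 counts. The other 22 libraries, with reference diet 4 left out, still had 12349 to 12794 genes when thinned to that total, so the depth of sequencing does not account for the loss. Among 1526 genes with a mean of 1 to 5 CPM in those libraries, 13.1% had 0 counts in low BCAA diet 8, against at most 1.97% in any other. Among genes above 20 CPM the share was 0.228% against at most 0.21%, and among genes of 0.1 to 1 CPM 51.1% against at most 12.3%. A library made from fewer distinct RNA molecules, then amplified, is consistent with these shares, and no biological explanation was tested because the labels give this pool no feature that the rest of its diet lacks.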

How the results depend on the processing

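Leaving out reference diet 4 and low BCAA diet 8, alone or with more changes, and the split without reference diet 4 were chosen only after the result was seen, and all other alternatives were fixed beforehand. The counts of genes called for low BCAA, high BCAA, any of the 3 diets and both altered diets (21, 2, 4 and 21) were 139, 21, 257 and 100 with DESeq2. They were 861, 30, 312 and 298 with limma voom and quality weights, and 92, 4, 24 and 61 with 1 surrogate variable. For high against low BCAA (0 with edgeR) DESeq2 gave 4 and voom 2. Without a filter the counts for low BCAA and both diets were 13 and 10, and with only the 16 samples compared 11 for low and 1 for high BCAA. DESeq2 size factors gave 14 for low BCAA and the same counts elsewhere. Without the 2 libraries there were 116 calls for low BCAA (9 risen, 107 fallen), 35 for any and 89 for both. With 1 surrogate variable besides there were 148, 41, 124 and 225, and without 4 more libraries 176, 1, 29 and 176. Those 4 were chosen for the highest CPM of CG34220 among the rest: reference diet 3, high BCAA diets 3 and 5 and low BCAA diet 4. All 21 low BCAA calls were kept with DESeq2, with voom, with 1 surrogate variable and without the 2 libraries; DESeq2 called 22 genes higher and 117 lower, and voom 310 higher and 551 lower. The lists called were 14, 1 and 14 for low, high and high against low BCAA with camera's preset correlation, and 0 in all other settings run. The cause of these shifts was not tested. Fewer samples were used where libraries were left out, yet without the 2 libraries the counts for low BCAA and both rose.

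With the replicate number as a block, 46 genes were called for low BCAA (18 of the 21 kept), 18 for any and 40 for both, and the block changed no other call count by more than 1.5 times. The numbers gave no pairing that held throughout: 10 of 24 pairs of the same number had deviations correlated above 0.1 (median 0.086, from -0.329 to 0.557). Among them were all 3 pairs of number 1 (0.306, 0.338 and 0.386). Still, 8 of 24 samples correlated best with their own number, against a mean of 2.99 with the numbers shuffled within diets (permutation p = 0.0166). Samples of the same number may thus be linked in part, which the main fit, the label shuffles and the random splits ignore.

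With 1 library left out in turn, the counts ran from 6 to 80 for low BCAA, 0 to 6 for high BCAA, 0 to 1 for high against low BCAA, 4 to 23 for any and 4 to 79 for both, and the lists called stayed at 0. For low BCAA there were 80 without reference diet 4, 69 without reference diet 1 or low BCAA diet 8 and 43 without low BCAA diet 4. There were 13 without reference diet 3, 12 without low BCAA diet 3 or high BCAA diet 8, and 10 without reference diet 5, 6 or 7 or low BCAA diet 1. There were 9 without low BCAA diet 6, 8 without low BCAA diet 5 and 6 without low BCAA diet 2. For high BCAA there were 6 without reference diet 1, 1 without reference diet 6 or high BCAA diet 6, 7 or 8, and 0 without reference diet 5 or 7 or high BCAA diet 1, 2, 3 or 4. The count for any diet was 23 without low BCAA diet 8, 19 without reference diet 1, 16 without low BCAA diet 4, 14 without reference diet 4 and 7 without low BCAA diet 7. The correlation of the diets ran from 0.381 (without low BCAA diet 4) to 0.679 (without high BCAA diet 3), was 0.547 over genes of at least 10 CPM, and turned to -0.083 when the reference libraries were split between the diets (-0.101 without reference diet 4).

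Of 14 named values that passed, 9 were lost in some alternative and 0 changed sign; of 43 that did not pass, 6 passed in some alternative and 17 changed sign. With 1 library left out, CG1275, Gagr, pippin, EndoA, FucT6 and CG9743 kept their low BCAA calls throughout. CG3168 lost its call without low BCAA diet 2 or 5 (adjusted p up to 0.0556), HPS4 without reference diet 5 or low BCAA diet 2 (0.0599), CG12256 without reference diet 7 or low BCAA diet 1, 2 or 6 (0.0586), and Ilp5 without reference diet 6 or low BCAA diet 2, 3, 5 or 6 (0.0657). Tango5 lost it without any 1 of 8 libraries (0.0843) and Obp99b without any 1 of 13 (0.123). With only the 16 samples compared, FucT6, CG12256, HPS4, Tango5 and Ilp5 (adjusted p up to 0.107) and EndoA on the high BCAA diet (0.128) no longer passed, and Obp99b did not with DESeq2 size factors or the block (up to 0.0739). Depth limits reference diet 4, where 3 counts are 20.4 CPM, so genes with lower means are not measured there.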

Other observations

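The fit without reference diet 4 and low BCAA diet 8, the joint test of both cell type scores, the tests of these scores on 36 genes and the random splits were chosen only after the result was seen, and so were the lists of endoplasmic reticulum genes and digestive enzymes. In that fit of 22 libraries (7 reference, 7 low and 8 high BCAA) 9 genes rose and 107 fell on the low BCAA diet. Among the rises were cpx, which encodes complexin (log2FC 0.22 ± 0.05, edgeR adjusted p = 0.024), shakB, an innexin of electrical synapses (0.32 ± 0.08, 0.039), and the transcription factor genes bi (0.30 ± 0.07, 0.038) and FoxK (0.49 ± 0.12, 0.043). Among the falls were the ferritin genes Fer1HCH, from 1129 ± 72.6 to 899 ± 68.8 CPM (-0.33 ± 0.07, 0.020), and Fer2LCH (-0.32 ± 0.07, 0.033), which encode the chains of the iron storage complex. Other falls were those of crq, a scavenger receptor gene in the hemocyte list, from 238 ± 46.2 to 151 ± 30.2 CPM (-0.66 ± 0.13, 0.014), LanB1, a laminin gene (-0.80 ± 0.18, 0.034), and pirk, a negative regulator of the Imd immune pathway (-1.20 ± 0.21, 0.0064). These genes were picked after their values were seen. As whole lists 0 of 37 passed on the low BCAA diet in this fit, where camera with an estimated correlation gave the smallest p for autophagy and lysosome (0.0253), insulin signalling (0.0426) and hemocytes (0.064), and 0.248 for antimicrobial genes (each adjusted p = 0.723).

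Some genes of the endoplasmic reticulum, noticed after the values were seen, were also among the falls. In the same fit Xbp1, the transcription factor of the unfolded protein response, fell from 523 ± 77.2 to 373 ± 56.9 CPM on the low BCAA diet (-0.49 ± 0.11, edgeR adjusted p = 0.032), and the chaperone genes Gp93 (-0.85 ± 0.19, 0.034), CaBP1 (-1.02 ± 0.21, 0.020), Grp170 (-0.45 ± 0.09, 0.014) and Manf (-0.51 ± 0.11, 0.031) fell with it. Of 53 tested genes in a list of endoplasmic reticulum folding and secretion written after this was seen, 49 lay below 0 on the low BCAA diet and 49 on the high BCAA diet, and 12 and 0 of them fell. With both altered diets against the reference 18 fell and the list median was -0.22. With all 24 libraries 45 and 47 lay below 0, and 1 fell on the low BCAA diet, 0 on the high BCAA diet and 5 with both. In the 22 libraries the 17 genes that prompted the list held 11 of the 12 low BCAA falls and 16 of the 18 with both (median -0.452). The 36 other genes held 1 and 2 of these falls (median -0.165 with both), and 0 and 0 in all 24 libraries.

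That these transcripts shifted as a group on both altered diets is a hypothesis. The test on the 36 members other than the 17 that prompted the list gave a camera p of 0.0629 with an estimated correlation (median log2FC -0.165, 32 of 36 below 0) in 22 libraries and 0.149 in all 24 (-0.123, 30 of 36). It was not independent of the choice of the list. The 36 were measured in the same libraries as the 17, and the 53 genes were correlated (0.511 in 22 libraries). The bound written beforehand counted a p of 0.05 or more against a group shift, but such a p excludes nothing, so that bound was wrong and the question stays open. Over these 36 genes the mean differed by -0.154 ± 0.0546 (log2, SE) on the altered diets, where the fat body and hemocyte marker scores differed by -0.582 ± 0.362 and -0.333 ± 0.169. With the fat body score as a covariate the difference was -0.0832 ± 0.0354, beyond 2 SE of 0, and with the hemocyte score -0.091 ± 0.0497, within 2 SE. With both, a test added afterwards, it was -0.0792 ± 0.0373, little beyond 2 SE. A mean of marker genes measures tissue content imprecisely, so a difference left after adjustment cannot decide whether tissue is the whole cause. Over all 53 genes these values were -0.175, -0.18 and -0.165, each beyond 2 SE, but 17 of the genes were chosen for their fall. Only the tests with a single score were first planned on all 53. Less fat body and fewer hemocytes in those pools therefore stay open. Untested causes also stay open: other secretory cells, a diet effect inside brain cells, and the reference libraries common to both diets.

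CG34220 ranged from 0.4 to 75400 CPM over 22 libraries and was the gene with most counts in reference diet 3 and high BCAA diets 3 and 5. Midgut tissue carried along in some pools could raise it together with digestive enzymes, but the Spearman rho with the mean of these enzymes was 0.239 (permutation p = 0.283) and the Pearson r 0.419 (permutation p = 0.0493), falling to 0.323 without reference diet 3 and high BCAA diet 3. Only 4 of 36 digestive enzyme genes were expressed enough to be tested. They summed to 3110 CPM in reference diet 3 and 1560 CPM in high BCAA diet 5, the highest sums of the 22 libraries, but to 412 CPM in high BCAA diet 3, close to the 418 CPM of high BCAA diet 8, where CG34220 was at 0.84 CPM. With so few markers, midgut tissue cannot be told apart from other sources of this transcript, and no biological explanation was tested.

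For the counts of called genes, 100 splits of the samples into groups of the same sizes were compared, the real one included. The 21 genes of low BCAA against reference were reached by 1 of 100 splits, the real one (highest other 18). Chance can be excluded at the level of 0.05 for this count taken alone, provided that samples of the same number were not linked, which the splits ignore. Without reference diet 4 and low BCAA diet 8, the 116 genes of low BCAA against reference were reached by 1 of 100 splits (highest other 1). Those libraries were left out after the data were seen and the rest are the same samples, so this is not a separate exclusion of chance. The 2 genes of high BCAA against reference were reached by 3 of 100 (highest other 14), without correction for the number of counts tested. Both calls also ended without reference diet 5, and 437 genes had an unadjusted p under 0.05 where chance gives 514. For the high BCAA count the splits thus do not exclude chance. Chance was not excluded for any of the 3 diets (4 genes, 8 of 100 splits, highest other 42), for both altered diets (21 genes, 5 of 100, highest other 95) or for high against low BCAA (0 genes, 100 of 100, highest other 1105). The split with 1105 genes, many times the real count, points to a structure of the samples, which was not tested further, and only 5 of the other splits called any gene. It put low BCAA diet 4 and high BCAA diets 3 and 5 on the same side, the libraries at 47.2, 48.6 and 47.3 on the first principal component without reference diet 4 and low BCAA diet 8, where the others of these diets lay at 18.6 or below. Together with reference diet 3, at 46.6 on that component, they were also the libraries with the highest CPM of CG34220 (15570 in low BCAA diet 4, the lowest of them). What sets these libraries apart was not tested.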
